A study of Arabidopsis thaliana with 6 samples.

How the data were processed

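Polyadenylated RNA was taken with oligo(dT) beads from total RNA of whole seedlings, copied into cDNA with random hexamers and sequenced, per the labels' protocols. There were 6 libraries, 3 of Col-0 and 3 of csu6-2, each from seedlings kept for 5 days in white light. The authors deposited a table per library with a gene identifier and a value for 32678 genes, without a header. HISAT2, edgeR 3.0.8 and the build TAIR10 are named in the submitters' processing notes, with no role given. The counting program, the gene lengths, the annotation, the strand setting and any filter are not given in the sources used here. Without the strand setting, a gene and an antisense or overlapping partner cannot be told apart, and very short RNAs have uncertain values.

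The unit of the deposited values was read from the values themselves as RPKM, which the authors rounded to 2 decimals. The values were not whole, and their totals differed between libraries (813352 to 836697), which TPM would not do. Multiplied by the exon length of each gene, they summed to nearly the same total in each library, with a coefficient of variation of 0.27% against 0.98% for the plain totals. The lowest values, multiplied by gene length, gathered near steps, with 48.4 to 57.1% of them within 0.1 read of 1, 2 or 3 reads and the rest between. These steps put the depth at 27.4 to 43.3 M gene-assigned reads per library (M, mega), an estimate with mean ± SD of 33.3 ± 8.71 M in Col-0 and 33.2 ± 4.16 M in csu6-2. The sources do not say whether reads or read pairs were counted. The estimate assumes that the most common low value is 2 reads. If pairs were counted and that value is 1 pair, the values are FPKM and the depth, in pairs, is lower than given. Counts were not recovered from the rounded values, so no interval for counting error is given. RPKM divides by the summed reads of a library, so a rise of a few abundant transcripts lowers the value of the other genes.

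The plan fixed before the data were examined assumed counts and named a test on counts for them. Because the values were RPKM, the plan's stated fallback was used for every result. Genes with a value of at least 1 in 3 or more libraries were kept (18885 of 32678), and log2(RPKM + 1) was compared between genotypes with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust, with statmod 1.5.0). All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. A log2 change is csu6-2 minus Col-0 on the log2(RPKM + 1) scale, which understates the change of genes of low level. Means and SDs are of RPKM.

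The 26 gene lists were fixed before the data were examined. They hold 454 entries for 451 genes, since 3 genes stand in 2 lists, and none was absent from the files. Identifiers were matched by locus tag to the TAIR10.1 reference annotation (31912 of 32678), which gave kinds of gene, exon lengths for 31904 identifiers, GC content and coordinates. For 17 list entries the symbol was not among the symbols and synonyms of the reference. That comparison does not tell another spelling from a wrong identifier, and 0 entries were dropped. Lists with at least 5 tested members (25) were tested with camera at a preset correlation of 0.01. Camera compares a list with the other tested genes, so its direction is relative to them. The median log2 change of all tested genes was -0.0675. Beside this test stand camera with an estimated correlation, which called 0 lists, and fry, which called 5 for a shift to a side and 23 for change in either direction. Fry tests a list against no change, not against the other genes. The list of seed storage genes had 3 tested members and no list test.

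The genes named in the text follow a rule set before the data were examined. It takes PIF4 and PIF5, then the 6 largest rises and 6 largest falls among protein-coding genes past the threshold with a mean of at least 5 in the higher group and no overlap between genotypes. It adds the 3 members of lowest adjusted p of each list with at least 3 called members, and at least 2 members of the PIF-induced, clock and light signalling lists. The rule was written for CPM and was applied to RPKM. Other members named in the text were chosen after their values were seen.

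The test was tried on simulated data with the levels and spread of the 18885 tested genes and 200 changed genes, over 10 runs. The changed genes were drawn from those with a mean level above 5 RPKM, so recovery at lower levels was not tried. It recovered 81.1% of genes changed by 1.5-fold and 99.1% of those changed by 2-fold, with 5.04% of calls false, when the spread of each gene was drawn from the fitted prior. With each gene's own moderated spread these were 90.4%, 98.8% and 9.01%. In 1 run a list shifted by 1.5-fold was called, and 0 unmoved lists passed. The simulated genes varied independently, whereas the estimated correlations of the real lists reached 0.542. That run therefore says nothing about false list calls among correlated genes.

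The alternatives were another pseudocount (0.1), no filter, removal of each library's trend with GC content and gene length (library medians kept), the replicate number as a block, and leaving out each library. GC content and length were known for 99.21% of the tested genes. Alternatives chosen after seeing the data were median-of-ratios scaling, scaling to a common total, a minimum value of 5, eBayes without trend and robust, nuclear genes alone, and a limma test against a log2 change of 1. No library was a copy of another, with at most 0.42% of tested genes at equal values in a pair.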

Results

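Transcript levels were measured by RNA sequencing of polyadenylated RNA from whole Arabidopsis thaliana seedlings kept for 5 days in white light. The seedlings were Col-0, the wild-type accession, or csu6-2, a mutant in COP1 SUPPRESSOR 6, with 3 libraries of each genotype. COP1 is an E3 ubiquitin ligase that holds back light-driven seedling development. Each library listed the RPKM (reads per kilobase of gene, scaled to the reads of the library) of the same 32678 genes. With the most common low value taken as 2 reads, the depth was estimated at 27.4 to 43.3 M gene-assigned reads per library (M, mega). The estimates were 29.2, 43.3 and 27.4 M in Col-0 and 37.5, 29.2 and 32.9 M in csu6-2. The first principal component held 50.71% of the variance and separated the genotypes. Pearson correlations across genes were 0.9906 to 0.9931 within a genotype and 0.9833 to 0.9886 between genotypes.

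The comparison of csu6-2 with Col-0 asked whether CSU6 holds down the transcripts of PIF4 and PIF5, basic helix-loop-helix transcription factors that promote hypocotyl growth and are opposed by phytochrome. Both were higher in the mutant. PIF4 (AT2G43010; chromosome 2, 17886101 to 17889087, plus strand, in the TAIR10.1 annotation) rose from 18.1 ± 2.61 RPKM in Col-0 to 38.7 ± 7.92 RPKM in csu6-2 (SD, n = 3 each), a log2 change of 1.05 (SE 0.16, adjusted p = 0.00576). PIF5 (AT3G59060; chromosome 3, 21827905 to 21830837, minus strand) rose from 15.7 ± 4.06 to 29.1 ± 3.27 RPKM, a log2 change of 0.87 (SE 0.16, adjusted p = 0.0112). For both genes all 3 mutant libraries lay above all 3 wild-type libraries. The PIF4 call held with any of the 6 libraries left out (highest adjusted p 0.0264), whereas PIF5 did not pass without Col-0 replicate 2 (log2 change 0.81, adjusted p = 0.0592) or without csu6-2 replicate 3 (log2 change 0.81, adjusted p = 0.0557). With the replicate number as a block in the limma fit, PIF5 did not pass either (adjusted p = 0.0656). It passed when the GC and length trend was also removed (adjusted p = 0.0473). PIF7 was also higher (10.8 ± 0.746 against 14.1 ± 1.44 RPKM, log2 change 0.35, adjusted p = 0.0282), but did not pass without Col-0 replicate 2, csu6-2 replicate 2 or csu6-2 replicate 3 (adjusted p = 0.118, 0.107 and 0.104). The other 4 members of the PIF family (PIF1, PIF3, PIF6 and PIF8) did not pass, with log2 changes of -0.23 to 0.24. Over the 7 members, camera gave an upward shift at adjusted p = 0.0031 (adjusted p = 0.257 with an estimated correlation between genes).

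**Figure D1:**
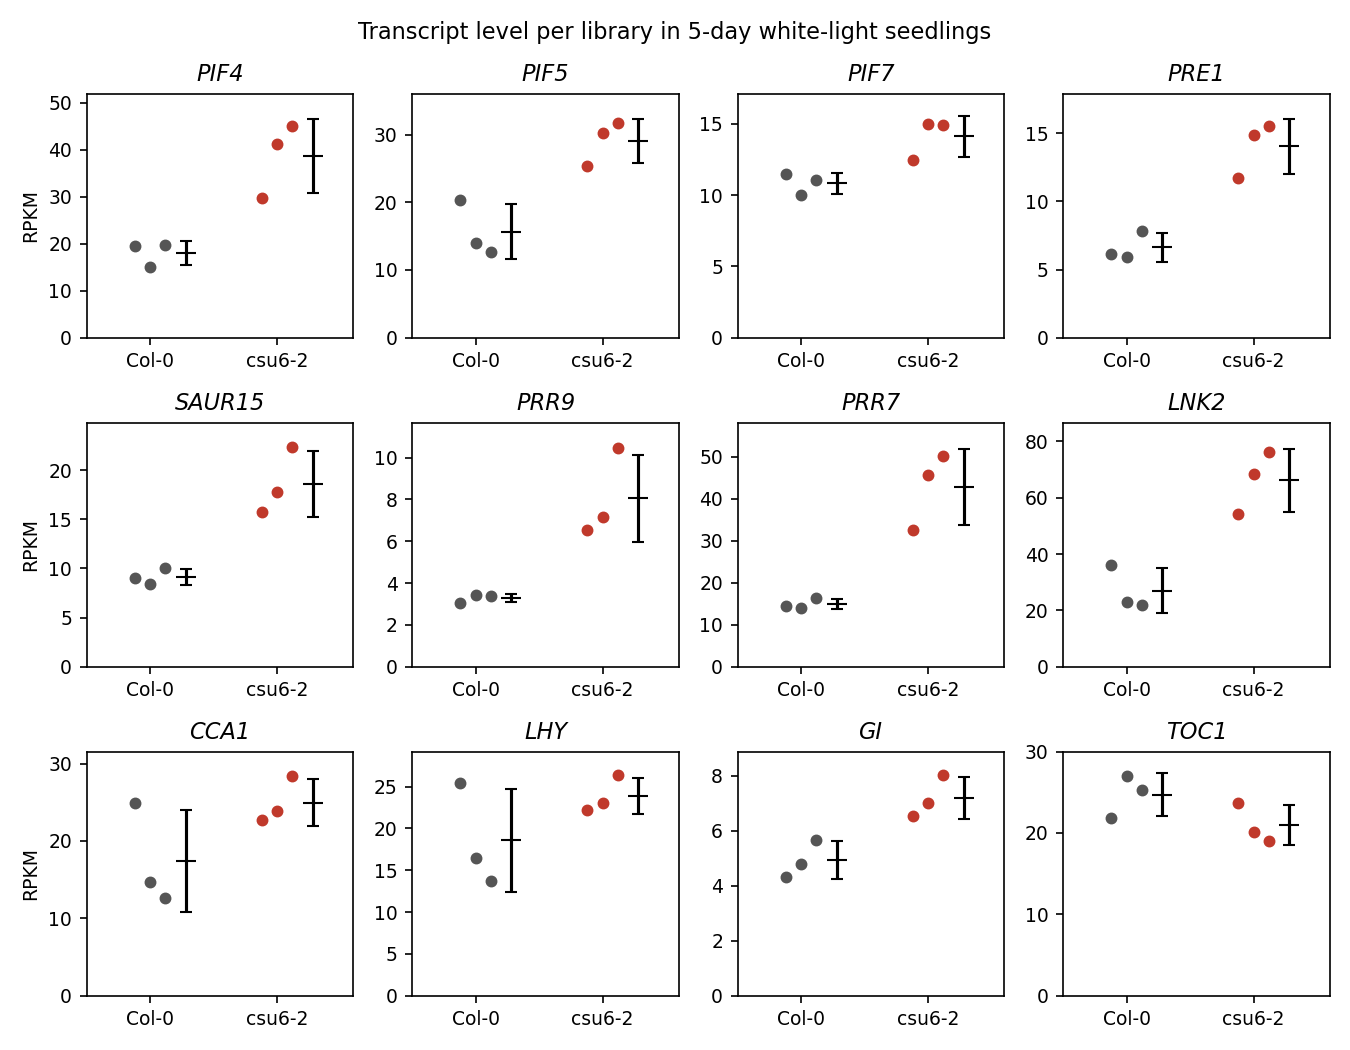
RPKM (y axis, from 0) of 12 transcripts in the 3 Col-0 libraries (grey) and the 3 csu6-2 libraries (red), with a dash and bar for the mean and SD. The mutant libraries lie above all wild-type libraries for PIF4, PIF5, PIF7, PRE1, SAUR15, PRR9, PRR7, LNK2 and GI, and overlap them for CCA1, LHY and TOC1.

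Across the transcriptome, 2442 of 18885 tested genes differed between the genotypes, 671 higher and 1771 lower in csu6-2. When the libraries were instead scaled by median-of-ratios factors, 1050 genes were higher and 1124 lower, so the split between directions depends on the scaling. Most changes were small, with a median absolute log2 change of 0.44 among the called genes. By at least 2-fold, 53 genes were higher and 45 lower (26 higher without csu6-2 replicate 3). These counts depend on the handling of low values, with 86 higher and 113 lower at a pseudocount of 0.1, and 42 higher and 27 lower at a minimum of 5 RPKM. The groups did not overlap for 6050 genes, 32.04% of those tested, where chance gives 10%. The count fell to 1279, 1394 and 1516 genes without Col-0 replicate 2, csu6-2 replicate 2 and csu6-2 replicate 3.

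Among protein-coding genes with at least 5 RPKM in the higher genotype and no overlap between genotypes, the largest fall belonged to AT3G02860, annotated as a zinc ion binding protein, on chromosome 3 at 625163 to 627491. It went from 17.3 ± 0.654 RPKM to 1.13 ± 0.36 RPKM (log2 change -3.12, SE 0.12, adjusted p = 4.23e-08). It was followed by AT5G26220, a ChaC-like gene (log2 change -1.62), AT1G08005 (-1.62), the orphan gene QQS (-1.61), the copper amine oxidase gene AT1G31690 (-1.53) and the mannose-binding lectin gene AT5G35940 (-1.35). The largest rise of these genes was that of the defensin-like gene AT1G34047, from 2.07 ± 0.0666 to 17.1 ± 2.8 RPKM (log2 change 2.55, SE 0.12, adjusted p = 1.28e-07). AT5G35480, of unknown function, rose by 2.27 on the log2 scale, and its neighbour on chromosome 5, MRU1 (AT5G35490), by 1.53. The thionin gene AT1G66100 rose from 43.5 ± 0.857 to 201.7 ± 54.7 RPKM (log2 change 2.15), the lipid transfer protein gene EARLI1 had a log2 change of 1.52 and the glutaredoxin gene AT3G21460 one of 1.48. AT5G26220 did not pass without Col-0 replicate 3 or without csu6-2 replicate 1, 2 or 3 (adjusted p = 0.088, 0.0593, 0.0752 and 0.0883), and QQS did not pass without csu6-2 replicate 3 (adjusted p = 0.0596). AT3G21460 did not pass without Col-0 replicate 2 or without csu6-2 replicate 2 or 3 (adjusted p = 0.0952, 0.0586 and 0.0546). The CSU6 locus is not given in the sources used here, so the mutated gene itself was not examined.

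**Figure D2:**
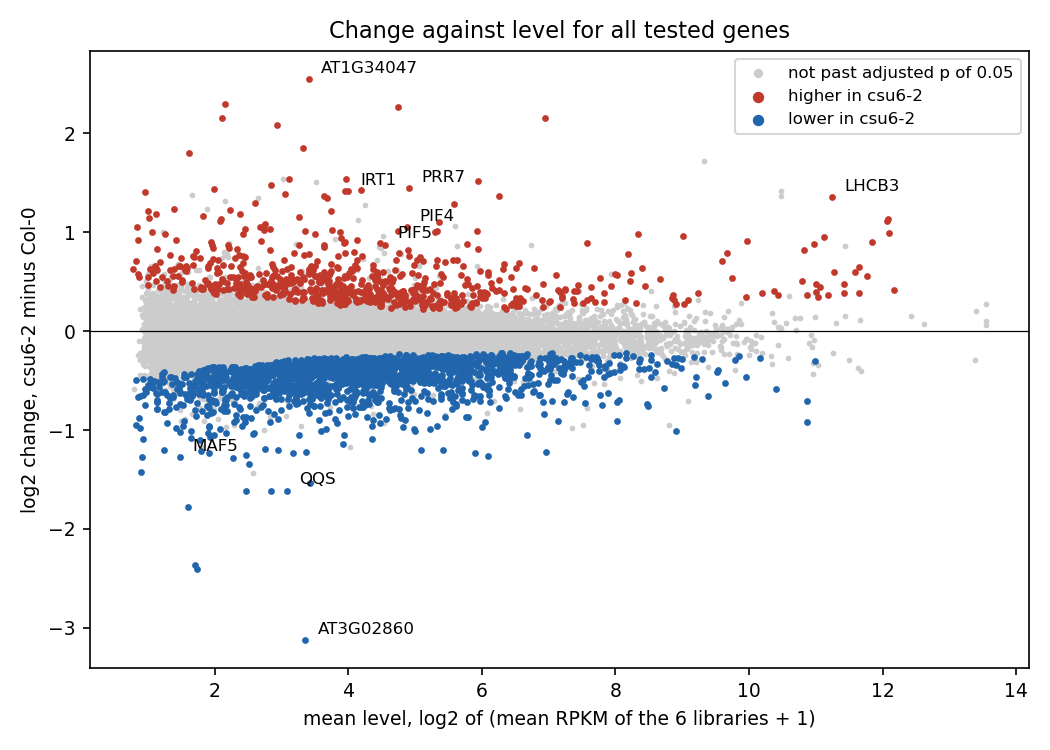
Log2 change, csu6-2 minus Col-0 (y axis), against the mean level of the 6 libraries (x axis, log2 of mean RPKM + 1), for the 18885 tested genes. Red points are the 671 genes higher and blue points the 1771 genes lower in csu6-2 at adjusted p under 0.05, and grey points are the rest.

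Of the 26 lists, that of auxin-responsive genes held the most called rises, with near-identical copies counted singly. Of 29 tested auxin-responsive genes, 19 were higher and 0 lower (21 and 0 adjusted over the list alone), with a median log2 change of 0.45 (camera adjusted p = 1.02e-16, and adjusted p = 0.257 with an estimated correlation). SAUR15 rose from 9.13 ± 0.792 to 18.6 ± 3.37 RPKM (log2 change 0.94), SAUR20 from 14.5 ± 2.12 to 27.8 ± 2.97 RPKM (0.89) and SAUR24 from 34.6 ± 0.423 to 58.23 ± 10.02 RPKM (0.72). SAUR19 to SAUR24 and SAUR61 to SAUR68 are near-identical families in which reads could be split between copies, so single members are uncertain. Most of the 19 called rises lie in these families, so their count and the list test do not rest on independent genes. GH3.2 and GH3.3, which conjugate auxin to amino acids, rose by 0.59 and 0.58 on the log2 scale. Among 20 tested PIF-induced and shade-induced genes, 3 were higher and 0 lower (8 and 0 adjusted over the list alone, 7 and 0 with median-of-ratios scaling; camera adjusted p = 0.000105, and adjusted p = 0.257 with an estimated correlation). These were PRE1, a growth-promoting helix-loop-helix gene (6.63 ± 1.07 to 14.04 ± 2.03 RPKM, log2 change 0.98), PAR2 (0.50) and the auxin synthesis gene TAA1 (0.30). PAR2 did not pass without Col-0 replicate 2 or 3 or without csu6-2 replicate 2 or 3 (adjusted p = 0.0689, 0.0548, 0.0864 and 0.0617). TAA1 passed in 1 of 6 fits with a library left out, and not without Col-0 replicate 1 or 2 or csu6-2 replicate 1, 2 or 3 (adjusted p = 0.0904, 0.199, 0.0938, 0.0832 and 0.145). The scaled fit added HAT1, PRE6, BEE1 and XTH15, whose log2 changes without it were 0.37, 0.31, 0.30 and 0.42 (adjusted p = 0.0519, 0.0592, 0.074 and 0.0799). Other PIF targets passed in neither, among them IAA29 (log2 change -0.02), YUC8 (-0.02) and ATHB2 (0.05).

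Genes for cell wall loosening moved in both directions. Of 20 tested, 8 were higher and 2 lower (11 and 3 adjusted over the list alone, 11 and 1 with median-of-ratios scaling; camera adjusted p = 1.17e-07 upward, and adjusted p = 0.257 with an estimated correlation). The expansin genes EXPA8 and EXPA11 rose by 1.01 and 0.65 on the log2 scale and the xyloglucan endotransglucosylase gene XTH17 by 0.76. XTH9 fell from 187 ± 9.97 to 120.2 ± 9.82 RPKM (log2 change -0.64). Of 15 gibberellin genes, 1 was higher and 2 lower, counts that were the same adjusted over the list alone (camera adjusted p = 0.714). The upward direction of that test is relative to the other tested genes. The median log2 change was -0.0573 in the list and -0.0675 over all tested genes, and the list mean was 0.00 to 2 decimals, negative in sign. GASA6, a gibberellin-regulated gene of cell elongation, rose from 349.3 ± 11.5 to 681.9 ± 35.6 RPKM (log2 change 0.96, adjusted p = 6.28e-06). GID1A (-0.32) and GASA4 (-0.27) were lower, but neither passed with median-of-ratios scaling (adjusted p = 0.0523 and 0.141). Without Col-0 replicate 2 or 3 or csu6-2 replicate 2 or 3, neither passed (adjusted p = 0.13, 0.0501, 0.104 and 0.1 for GID1A and 0.182, 0.0906, 0.175 and 0.117 for GASA4). The 11 tested ethylene genes were shifted upward as a list (1 higher and 0 lower, also adjusted over the list alone, 2 and 0 with median-of-ratios scaling; camera adjusted p = 0.0151, and adjusted p = 0.257 with an estimated correlation). Of 11 brassinosteroid genes only BAS1, which inactivates brassinosteroids, passed at all genes tested (log2 change 0.48; 1 higher and 1 lower adjusted over the list alone, 2 and 0 with median-of-ratios scaling; camera adjusted p = 0.108). BAS1 did not pass without Col-0 replicate 3 or csu6-2 replicate 1, 2 or 3 (adjusted p = 0.0846, 0.0588, 0.0504 and 0.0949).

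Of 14 tested clock genes that peak in the morning, 5 were higher and 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 2.17e-06, and adjusted p = 0.257 with an estimated correlation). PRR7 rose from 14.9 ± 1.25 to 42.8 ± 9.14 RPKM (log2 change 1.44), PRR9 from 3.27 ± 0.195 to 8.04 ± 2.1 RPKM (1.06), LNK1 from 12.2 ± 1.61 to 20.8 ± 3.58 RPKM (0.72), LNK2 had a log2 change of 1.28 and LNK4 one of 1.42. LNK2 did not pass without Col-0 replicate 2 or 3 or csu6-2 replicate 2 or 3 (adjusted p = 0.0857, 0.0554, 0.0624 and 0.0888), nor LNK4 without Col-0 replicate 2 or csu6-2 replicate 2 or 3 (adjusted p = 0.0913, 0.06 and 0.0856). The other 9 did not pass, among them the central morning repressors CCA1 and LHY (log2 changes 0.54 and 0.39, adjusted p = 0.247 and 0.307) and RVE2 (-0.78, adjusted p = 0.134). The Col-0 values of CCA1 and LHY were spread widely, with CCA1 at 24.9, 14.7 and 12.6 RPKM and LHY at 25.5, 16.5 and 13.7 RPKM in replicates 1, 2 and 3. Of 11 afternoon- and evening-phased genes, GI was higher (log2 change 0.47, adjusted p = 0.0166) and ELF4 lower (-0.27, adjusted p = 0.0449), and 9 did not pass (camera adjusted p = 0.56; 1 higher and 3 lower adjusted over the list alone). GI did not pass without Col-0 replicate 1 or 2 or csu6-2 replicate 2 or 3 (adjusted p = 0.0549, 0.0595, 0.0523 and 0.0755). ELF4 did not pass with median-of-ratios scaling (adjusted p = 0.188), or without Col-0 replicate 2 or 3 or csu6-2 replicate 1, 2 or 3 (adjusted p = 0.104, 0.159, 0.0842, 0.135 and 0.0899). Without Col-0 replicate 1 the afternoon and evening list as a whole was lower (camera adjusted p = 0.0187), while over all 6 libraries it had adjusted p = 0.848 with an estimated correlation.

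Light-harvesting transcripts were among the most abundant that changed. The list of light-harvesting and Rubisco small subunit genes took 7.12 ± 0.92% of the summed RPKM in Col-0 and 10.6 ± 1.02% in csu6-2 (SD, n = 3 each). Of its 22 genes, 12 were higher and 1 lower (16 and 2 adjusted over the list alone; camera adjusted p = 1.85e-14, and adjusted p = 0.257 with an estimated correlation). LHCB6 rose from 1529 ± 256.8 to 2949 ± 412.1 RPKM (log2 change 0.95), LHCA3 from 1313 ± 121.9 to 2327 ± 373.5 RPKM (0.82) and LHCB4.1 from 1959 ± 219.5 to 2969 ± 300.6 RPKM (0.60). LHCB3 had a log2 change of 1.36. LHCB3 did not pass without Col-0 replicate 2 or 3 or csu6-2 replicate 3 (adjusted p = 0.0569, 0.0537 and 0.11). LHCB4.3 was lower (-0.73), but not past the threshold without Col-0 replicate 2 or 3 or csu6-2 replicate 2 (adjusted p = 0.0661, 0.0523 and 0.0635), and none of the 4 Rubisco small subunit genes passed (log2 changes -0.38 to 0.20). The LHCB1 and Rubisco small subunit copies share long stretches of sequence, so their single values are uncertain. Of 19 chlorophyll synthesis genes, 3 were higher and 2 lower (6 and 5 adjusted over the list alone, 5 and 1 with median-of-ratios scaling; camera adjusted p = 0.106). The magnesium chelatase subunit gene CHLH rose from 240.7 ± 39.5 to 360.1 ± 9.18 RPKM (log2 change 0.59). GSA1 (-0.33) and the transcription factor gene GLK1 (-0.32) were lower, although GLK1 did not pass with median-of-ratios scaling (adjusted p = 0.0994) or without Col-0 replicate 1 or 3 or csu6-2 replicate 2 (adjusted p = 0.0696, 0.0645 and 0.104). The chlorophyll synthesis list was higher without Col-0 replicate 1 (camera adjusted p = 0.0242) and without csu6-2 replicate 3 (0.0482), while over all 6 libraries it had adjusted p = 0.501 with an estimated correlation.

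Of 35 light receptor and signalling genes, 6 were higher and 1 lower (6 and 2 adjusted over the list alone, 6 and 0 with median-of-ratios scaling; camera adjusted p = 0.0031 upward, and adjusted p = 0.354 with an estimated correlation). The early light-induced genes ELIP1 and ELIP2 rose from 16.9 ± 1.5 to 34.9 ± 2.61 RPKM and from 9.68 ± 0.411 to 18.9 ± 2.61 RPKM (log2 changes 1.01 and 0.89), and BBX24, a B-box regulator of light responses, had a log2 change of 0.55. HY5, COP1 and PHYB did not pass (log2 changes 0.07, -0.08 and 0.05). Of 22 flavonoid and anthocyanin genes, 5 were higher and 0 lower (8 and 1 adjusted over the list alone, 8 and 0 with median-of-ratios scaling; camera adjusted p = 2.04e-05, and adjusted p = 0.257 with an estimated correlation). They included TT19, a glutathione transferase needed for anthocyanin accumulation (log2 change 0.56), CHIL (0.26) and MYBL2, a repressor of the pathway (0.90). MYBL2 did not pass without Col-0 replicate 2 (adjusted p = 0.0646). CHIL passed in 0 of 6 fits with a library left out, with adjusted p = 0.0536, 0.0513 and 0.146 without Col-0 replicates 1, 2 and 3 and 0.0663, 0.107 and 0.108 without csu6-2 replicates 1, 2 and 3.

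Of 16 iron deficiency genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 2.51e-06, and adjusted p = 0.257 with an estimated correlation). The root iron transporter gene IRT1 rose from 7.74 ± 0.977 to 22.2 ± 0.339 RPKM (log2 change 1.41, adjusted p = 2.44e-06), the ferric reductase gene FRO2 from 1.68 ± 0.481 to 4.74 ± 0.321 RPKM (1.11) and the regulator BHLH38 from 3.14 ± 0.713 to 7.64 ± 1.95 RPKM (1.05). FIT, an activator of IRT1 and FRO2, did not pass (log2 change -0.02). Of 11 energy starvation genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.00208, and adjusted p = 0.375 with an estimated correlation), with log2 changes of 0.63 for DIN2, 0.50 for TPS11 and 0.29 for TPS10. DIN2 did not pass without Col-0 replicate 2 or csu6-2 replicate 3 (adjusted p = 0.0585 and 0.0579), nor TPS11 without Col-0 replicate 2 or 3 or csu6-2 replicate 1 (adjusted p = 0.0633, 0.0585 and 0.0647). TPS10 passed in 1 of 6 such fits, and not without Col-0 replicate 1, 2 or 3 or csu6-2 replicate 1 or 3 (adjusted p = 0.057, 0.13, 0.127, 0.113 and 0.145). Of 8 phosphate starvation genes, RNS1 was higher (log2 change 0.90) and SPX1 (-0.40) and SQD1 (-0.36) were lower, the same counts as adjusted over the list alone (camera adjusted p = 0.32). SPX1 and SQD1 did not pass with median-of-ratios scaling (adjusted p = 0.06 and 0.0834). Without Col-0 replicate 2 or csu6-2 replicate 1 or 3, adjusted p was 0.0985, 0.0536 and 0.0849 for SPX1 and 0.104, 0.065 and 0.0835 for SQD1.

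Several stress and development genes were lower. The adjacent floral repressor genes MAF5 and MAF4 fell from 2.94 ± 0.32 to 0.633 ± 0.174 RPKM and from 4.99 ± 0.167 to 1.94 ± 0.308 RPKM (log2 changes -1.27 and -1.03). MAF5 was under 1 RPKM in all csu6-2 libraries (0.5, 0.57 and 0.83), so it was tested only through its Col-0 values. It was not tested when a Col-0 library was left out, and passed in the 3 fits without a csu6-2 library. MAF1 was also lower (-0.35), a call lost without Col-0 replicate 2 (adjusted p = 0.0528). The 17 flowering-time genes as a list did not move together (1 higher and 4 lower, 2 and 4 adjusted over the list alone; camera adjusted p = 0.906), and FLC did not pass (log2 change -0.11). Among 19 jasmonate genes, LOX2 fell from 186.4 ± 17.7 to 113 ± 13.4 RPKM (log2 change -0.72), and VSP1 (-0.76) and LOX3 (-0.63) were lower (0 higher and 3 lower, 2 and 8 adjusted over the list alone; camera adjusted p = 0.106, and 0.05 without csu6-2 replicate 2; over all 6 libraries, adjusted p = 0.373 with an estimated correlation and 0.0398 downward by fry). Of 20 cold and abscisic acid genes, 1 was higher and 4 lower, as adjusted over the list alone (camera adjusted p = 0.32; lower at 0.0323 without csu6-2 replicate 3 and 0.0356 with a minimum of 5 RPKM, while over all genes and libraries it had adjusted p = 0.784 with an estimated correlation). KIN1 (-0.62) and KIN2 (-0.70) are close neighbours with similar sequence and therefore uncertain singly, and the phosphatase gene HAB1 had a log2 change of -0.46. KIN2 did not pass without csu6-2 replicate 1, 2 or 3 (adjusted p = 0.0521, 0.0693 and 0.0912), nor HAB1 without Col-0 replicate 1 or 2 or csu6-2 replicate 2 or 3 (adjusted p = 0.0668, 0.1, 0.106 and 0.0742). Of 16 glucosinolate genes, 1 was higher and 3 lower, as adjusted over the list alone. Camera gave adjusted p = 0.639, upward relative to the other tested genes, with a list median of -0.02 and a mean of -0.04. CYP79B2 (-0.38), CYP83B1 (-0.34) and MYB34 (-0.34) were lower, and the last 2 did not pass without Col-0 replicate 2 (adjusted p = 0.05 and 0.0687) or csu6-2 replicate 2 (adjusted p = 0.0536 and 0.0747). Of 8 salicylic acid defence genes only PR5 passed, at a lower level (log2 change -0.74; camera adjusted p = 0.747), and it did not pass without Col-0 replicate 1 or 2 or csu6-2 replicate 1 or 3 (adjusted p = 0.0511, 0.063, 0.0697 and 0.0616).

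Of 6 tested heat shock genes, 0 were higher and 3 lower (0 and 4 adjusted over the list alone), namely HSP70-4 (log2 change -0.60), ROF2 (-0.51) and HSP90.1 (-0.47). The list was lower by camera (adjusted p = 0.0151, and adjusted p = 0.375 with an estimated correlation), but not without Col-0 replicate 3 (adjusted p = 0.082). ROF2 was lost without Col-0 replicate 2 (adjusted p = 0.0582) and HSP90.1 without Col-0 replicate 1 or 3 or csu6-2 replicate 2 (adjusted p = 0.0527, 0.0664 and 0.0798). Of 9 stomatal lineage genes, 0 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.0232, adjusted p = 0.354 with an estimated correlation, and adjusted p = 0.145 without csu6-2 replicate 1). The 3 act early in the lineage. TMM fell from 8.98 ± 0.802 to 4.39 ± 0.638 RPKM (log2 change -0.89), SPCH from 8.27 ± 0.676 to 4.81 ± 0.845 RPKM (-0.68) and EPF2 from 13.4 ± 0.862 to 8.19 ± 1.52 RPKM (-0.66), while the later genes MUTE and FAMA did not pass (-0.26 and -0.12). Of 10 cell division genes, the cytokinesis gene KNOLLE (-0.44) and CYCB1;2 (-0.35) were lower (0 and 5 adjusted over the list alone; camera adjusted p = 0.0136, adjusted p = 0.425 with an estimated correlation, and adjusted p = 0.0504 without Col-0 replicate 2). Of 13 root marker genes, SHR alone passed, at a lower level (log2 change -0.38). The list had camera adjusted p = 0.292, upward relative to the other tested genes, with a median of -0.08 and a mean of 0.03. Without csu6-2 replicate 2 the list was upward at camera adjusted p = 0.0239. Over all 6 libraries it had adjusted p = 0.784 with an estimated correlation. SHR did not pass without Col-0 replicate 2 or 3 or csu6-2 replicate 2 (adjusted p = 0.05, 0.0674 and 0.0813). The 3 tested seed storage genes did not pass.

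**Figure D3:**
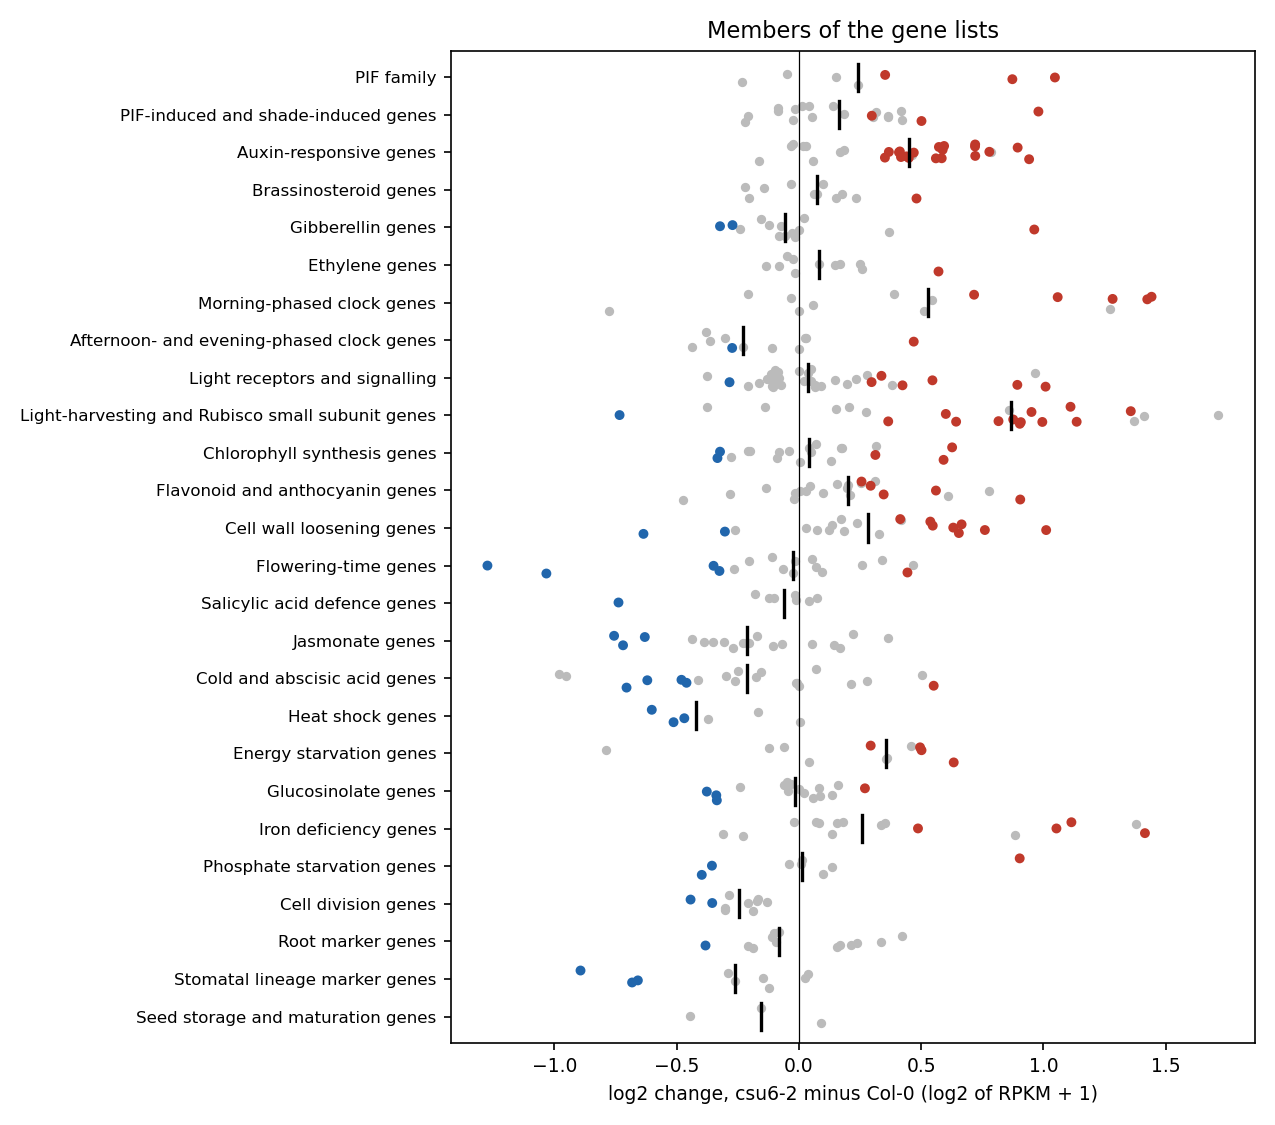
Log2 change, csu6-2 minus Col-0 (x axis), of the tested members of the 26 gene lists (rows), with red and blue points for members higher and lower at adjusted p under 0.05, grey points for the rest and a black bar at each list's median. The medians range from -0.42 for heat shock genes to 0.87 for light-harvesting and Rubisco small subunit genes.

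In all, camera placed 11 lists higher and 3 lower than the other tested genes, out of 25 lists tested. With an estimated correlation 0 passed, and 3 lists had an unadjusted p under 0.05. These p-values measure the spread between these samples, since no source used here says that the replicates came from separate cultures.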

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

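The scaling, the minimum of 5, the variance model, nuclear genes alone and the test against a log2 change of 1 were alternatives chosen after seeing the data. The planned edgeR, DESeq2 and voom fits were not run, since they need counts. PIF4 passed, with its direction kept, in each alternative but the test against a log2 change of 1, which it did not pass. PIF5 kept its direction in each of them, with leave-one-out values of 0.75 to 1.06, and those of PIF4 were 0.93 to 1.22. The number of called genes was 1279 to 2324 with a library left out (389 to 674 higher, 859 to 1790 lower; 26 to 77 higher and 33 to 67 lower by at least 2-fold), and the list calls were 13 to 16. Of the 2442 called genes, 1221 were called again without Col-0 replicate 2, and 0 changed direction in any setting. Whether the replicate numbers pair the samples was left open. The same-number correlations of deviations were 0.204, 0.051 and 0.221, and those of different numbers ran from -0.304 to 0.121. Col-0 replicate 2 correlated best with csu6-2 replicate 1 (0.121). With the number as a block, 2969 genes were called, and PIF5 (0.87) had an adjusted p of 0.0656 against 3.43e-05 to 0.0592 with a library left out; MYBL2 (0.0656) and AT5G26220 (0.0502) did not pass either. The cause was not tested.

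With a pseudocount of 0.1, 86 genes were higher and 113 lower by at least 2-fold, because a smaller pseudocount widens the change of low genes. With a minimum of 5, 27 genes were lower by at least 2-fold, with fewer low genes tested. Median-of-ratios scaling gave 1050 higher and 1124 lower genes. Tested against a log2 change of 1, 8 genes passed, 5 higher (AT1G34047, AT5G35480, AT4G04293, AT3G15310 and AT1G19376) and 3 lower (AT3G02860, AT2G15750 and AT4G01980), a stricter question. Of the 14 list calls, 0 remained with an estimated correlation, which widens the error. Fry called 5 lists, 4 of these 14 (auxin, light-harvesting, cell wall and stomatal genes) and the jasmonate genes (0.0398). Directions turned only for lists that did not pass. Flowering-time genes turned upward with no filter (adjusted p = 0.98), with the replicate block (0.94, and 0.918 with the GC and length trend also removed), with a minimum of 5 (0.487) and in 4 of 6 fits with a library left out (0.517 to 0.921, in a range of 0.517 to 0.973). Salicylic acid genes turned in 2 such fits (0.966 and 0.993, range 0.431 to 0.993), gibberellin genes in 1 (0.823, range 0.508 to 0.897; also 0.898 with a minimum of 5) and evening clock genes in 1 (0.731, range 0.0187 to 0.757). With fry, glucosinolate (0.661) and root marker (0.988) genes had the other direction. Fry tests against no change and camera against the other tested genes, so the directions answer different questions. With no filter, where more genes share the adjustment, PIF7, PAR2, TAA1, GID1A, GASA4, ELF4, GLK1, CHIL, HAB1, TPS11, TPS10, SPX1 and SQD1 did not pass (adjusted p = 0.0528 for TPS11 to 0.0879 for GASA4). GASA4 and ELF4 did not pass with the GC and length trend removed (0.0816 and 0.0579; 0.0913 and 0.0506 with the block), nor TAA1, GASA4 and TPS10 with a common total (0.057, 0.0501 and 0.0642). With eBayes run without trend and robust, 1954 genes were called, and PIF7 (0.052), TAA1 (0.0771), GID1A (0.0566), GASA4 (0.102), ELF4 (0.101), GLK1 (0.0649), CHIL (0.0907), HAB1 (0.0594), TPS10 (0.0639), SPX1 (0.0535) and SQD1 (0.0631) did not pass. Of 69 other named genes, 25 crossed the threshold in at least 1 setting and 0 turned.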

Other observations

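The gene groups in this part were chosen after seeing the data, from 328 annotation terms of which 17 passed, and so were the tests of evening harvest, of root tissue and of classes of GC content and length. Of 48 tested genes annotated to nucleosome assembly, 0 were higher and 24 lower, with a median log2 change of -0.27 (-0.19 with median-of-ratios scaling; limma camera adjusted p = 1.2e-06, and adjusted p = 0.995 with an estimated correlation). The histone H2B gene HTB2 went from 510 ± 63.0 to 339.6 ± 17.8 RPKM (SD, n = 3 each; log2 change -0.58) and HTB1 from 98.3 ± 7.63 to 69.7 ± 5.05 RPKM (-0.49). The H2A gene HTA13 went from 138.2 ± 6.09 to 104.1 ± 3.81 RPKM (-0.40). Histone genes are near-identical copies, so single members are uncertain.

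Of 23 tested genes located to the nucleoid, 1 was higher and 12 lower (median log2 change -0.36, and -0.28 with median-of-ratios scaling; camera adjusted p = 2.8e-06, and adjusted p = 0.995 with an estimated correlation). The iron superoxide dismutase genes FSD2 and FSD3, whose products associate with the plastid-encoded RNA polymerase, went from 85.8 ± 6.23 to 51.9 ± 1.54 RPKM (log2 change -0.71) and from 98.7 ± 5.77 to 62.0 ± 1.79 RPKM (-0.66). PTAC12, another such gene, had a log2 change of -0.59, PTAC3 one of -0.50 and the DNA-binding protein gene WHY1 one of -0.65. Among 49 small nucleolar RNA genes 8 were higher and 1 lower, values that rest on very short transcripts.

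A few pseudogenes were nearly switched between the genotypes. AT2G15750 stood at 4.53, 3.87 and 5.4 RPKM in the Col-0 libraries and at 0, 0.08 and 0.07 in csu6-2, and AT4G01980 at 3.67, 4.96 and 4.69 against 0.09, 0.07 and 0. The opposite held for AT3G15310, at 0.45, 0.68 and 0.63 in Col-0 and 6.26, 6.14 and 5.71 in csu6-2, and for AT4G04293, at 0.39, 0.43 and 0.68 against 6.25, 6.94 and 5.92. The protein-coding gene AT3G02860 stood at 17.44, 17.9 and 16.61 against 1.14, 0.76 and 1.48.

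The 2442 genes called for the genotypes compare with 0 for each of the 9 other splits of the 6 libraries into 3 and 3, by the same limma test, 1 split in 10 reaching that count. At an unadjusted p under 0.05 the genotypes gave 5266 genes and the other splits at most 1527. With 10 splits a share under 0.05 cannot be reached. Each other split mixes the genotypes, so their differences enter its residual spread, and its 0 calls do not measure the rate of false calls.

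More genes were lower than higher, 72.52% of those called. With each library's trend with GC content and gene length removed the share was 72.01%, which decides nothing, since that correction kept the library medians. In 9 classes of GC content and exon length the lowest share was 66.67% (exact 95% interval 60.14 to 72.75%, just above the bound of 60% set for it). The excess of lower genes was thus present in all 9 classes. That interval takes the genes as independent, although they share the same 6 libraries, so it is too narrow. It therefore cannot decide on a trend that lowers some classes and not others as the whole of the excess. A shift in composition may account for much of the excess: with median-of-ratios scaling the share was 51.7%, and light-harvesting and Rubisco genes took 10.6% of the RPKM in csu6-2 against 7.12% in Col-0. Median-of-ratios scaling itself assumes that most genes did not change, so a real fall of many genes stays open and was not tested.

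Called rises were found together among light-harvesting genes, morning clock genes and PIF4 and PIF5. A later morning harvest of the mutant would lower CCA1 and LHY, whose mean log2 change was 0.47. Neither gene passed, and their csu6-2 values overlapped those of Col-0. RVE2, of the same morning list, was lower but did not pass either. Its values were 240.66, 244.12 and 225.23 RPKM in Col-0 and 205.12, 115.44 and 109.69 in csu6-2. These genes therefore do not decide on a later morning harvest. A smaller share of root tissue would lower root markers by about the rise of the light-harvesting and Rubisco list (median log2 change 0.87). Their median was -0.0815 (SD 0.24 over 13 genes), near the -0.0675 of all tested genes, and -0.0181 with median-of-ratios scaling. These values argue against less root tissue as the source of that rise. The Rubisco small subunit genes also did not rise with the light-harvesting genes. A harvest of csu6-2 at an earlier phase of the afternoon could give the same pattern, and the 6 evening genes left it open, with a median log2 change of -0.0543 (SD 0.27). Over the fixed list of 11 afternoon- and evening-phased genes, which holds these 6, the median was -0.227, nearer to the fall that such a harvest would give. Within Col-0, replicate 1 had the highest CCA1 (24.9 against 14.7 and 12.6 RPKM), LNK2 (36.15 against 22.96 and 22.03), PIF5 (20.3 against 14 and 12.7) and LHCB3 (1779.9 against 1149.9 and 1180.4), whereas PIF4 (19.48, 15.04 and 19.64 RPKM in replicates 1, 2 and 3) and PRR7 (14.46, 13.95 and 16.32) were highest in replicate 3 and PRR9 (3.05, 3.41 and 3.36) was lowest in replicate 1. Members of this pattern thus did not all vary alike between Col-0 libraries, although some of these gaps were small. Within csu6-2, replicate 1 was the lowest for each of these genes. In replicates 1, 2 and 3 PIF4 stood at 29.8, 41.16 and 45.03 RPKM, and PRR7 at 32.59, 45.67 and 50.19. LNK2 stood at 54.13, 68.39 and 76.15 RPKM and LHCB3 at 2662.15, 4000.46 and 3816.74. A component shared by these genes between libraries therefore stays open and was not tested. Neither the hour of harvest nor whether the white light was constant or cycled is given in the sources used here. An effect of the genotype remains among the open explanations.

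Genes changed at least 2-fold were looked at along the chromosomes for a linked segment that differs between the lines. The fullest window of 2 Mb, on chromosome 5 from 22000001 to 24000000 in TAIR10.1, held 7 of 98 such genes, equal to the 95th percentile (7) of 10000 random draws of tested genes, and 18.83% of the draws were as full. The rule set before the data were examined counted a window no fuller than that percentile against a segment. Here a count equal to the percentile was taken as undecided instead. A window this full was common in random draws, so no gathering beyond them was found. A segment that holds few such genes would escape this test.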
